A study of Homo sapiens with 12 samples.

How the data were processed

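RNA from human primary adipocytes, prepared from adipose tissue and treated with a differentiation cocktail, was sequenced in 12 libraries that fall into 4 groups of 3. The groups are wild-type control cells, CUX1 knockout cells, cells overexpressing GFP and cells overexpressing CUX1. Sequencing was paired-end, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate donors or cultures, so the p-values below measure only the spread between these libraries, which may be technical.

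The deposited values are 2 tables of estimated counts per gene symbol, with the control and CUX1 knockout libraries in the first and the GFP and CUX1 overexpression libraries in the second. Trim Galore 0.6.5, kallisto 0.46.1, R 4.3.0 and edgeR 4.0.2 are named in the submitters' processing notes, together with the genome build GRCh38 (hg38). kallisto assigns reads to transcripts by pseudoalignment and yields estimated counts that need not be whole. Of the deposited values above 0, 0.044% were whole numbers to within 1e-06, which shows that they are estimates and not tallies of reads. How the authors summed transcripts to genes, whether they rescaled these counts for transcript length, and which transcript annotation they used are not given in the sources used here. Strand was also not given, so overlapping and antisense genes are not separable, and reads of near-identical paralogs or pseudogenes are divided by kallisto's estimate. Each table lists the same 35483 symbols, and 27681 of them (78.01%) match exactly 1 gene of GENCODE 29, which was used for coordinates on GRCh38. Every column of both tables was assigned to a sample by the library name in the labels.

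The total estimated count per library was 25176517 to 31185886 for control, 25153116 to 28654800 for CUX1 knockout, 14013303 to 18133184 for GFP and 20198626 to 28289934 for CUX1 overexpression. At these depths 3 counts correspond to 0.0962 to 0.214 CPM (counts scaled to a common library total), and levels below this were taken as not detectable. Where a gene had 0 counts in all 3 libraries of a group, a fold change is given as a bound computed against 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with an exact 95% Poisson interval. Such limits cover counting error only, because PCR copies are not independent molecules.

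The estimated counts were rounded to whole numbers, and each comparison was fitted alone over its 6 libraries. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), scaled by TMM, and tested two-sided with edgeR's quasi-likelihood F test in R 4.3.3. Calls required a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are treated over control, and their standard errors (SE) were approximated as the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM with the SD over 3 libraries. Because the tables were scaled apart, levels of the 2 experiments are set side by side only where this is stated. The difference of the knockout and overexpression effects was tested as a contrast in 1 fit over all 12 libraries. Calls shared by both comparisons were counted by direction and tested with two-sided Fisher's exact tests over genes tested in both. The comparisons share no library.

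Gene lists (30, with 562 members, all found in the tables and 4 of them under an older symbol) were fixed before the data were examined. They cover adipocyte function, progenitor and matrix genes, signalling responses, RNA composition and markers of other cell types. Each list with at least 5 tested members was tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. camera asks whether the genes of a list move relative to all other genes. The test was repeated with a correlation estimated from the data and with fry, which asks whether the genes of a list move on balance one way.

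The rule for the genes named in the text was fixed before the data were examined. It takes CUX1; the 10 largest increases and 10 largest decreases per comparison among called genes with mean log2 CPM of at least 1, complete separation of the 3 treated from the 3 control libraries, and a symbol that is not a clone or placeholder name; up to 4 members with the smallest adjusted p from each list that has 3 or more called members or is called by camera; and the 5 genes with the smallest larger adjusted p per direction pattern among genes called in both comparisons. Genes of the Y chromosome and XIST were never named. Other list members are named where a list is described. Some genes that the rule takes are not reported here.

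The libraries of each group were compared before averaging. Over the 12 within-group pairs, chi-square per degree of freedom was 8.43 to 16.5 for genes with at least 20 counts in the pair. These values lay above sampling noise in every pair. Pearson's correlation of log2 CPM across genes was 0.967 to 0.977. Each library was counted as its own replicate, but spread above sampling noise does not tell separate cultures from repeat preparations of the same culture. The steps were tested on simulated counts drawn from the real means, dispersions and library sizes, with a seeded set of genes changed by known folds. For the simulated knockout comparison (13606 genes), 32.8% of genes changed by 0.5 on the log2 scale, 62.7% of those changed by 1 and 92.4% of those changed by 2 were called, and 7 unchanged genes were called. For the simulated overexpression comparison (14012 genes) these shares were 26.9%, 65.7% and 92.4%, with 6 unchanged genes called. For the difference of effects (13494 genes), 114 of 128 genes simulated to differ by at least 2 were called with the right sign, and 24 unchanged genes were called. A planted list was found in both simulated comparisons (27 and 28 lists), beside 1 other list in each. Counts were drawn without correlation between genes, and per comparison 67, 67 and 66 genes were changed by 0.5, 1 and 2. The simulation therefore does not test the list calls at the correlations estimated from the data. Nor does it test the scaling where many genes change, as with overexpression.

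The alternatives fixed before the data were examined were RLE factors, no low-count filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, omission of each library in turn, a limit of at least 2-fold, and 1 fit over all 12 libraries. Added after the data were seen were a fit to unrounded counts, a fit without scaling factors, and a fit after thinning each comparison to its smallest library. Other molecular data of the study were not analysed here.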

Results

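Transcriptomes of human primary adipocytes treated with a differentiation cocktail were measured by RNA-seq in 12 libraries, 3 each from control cells, CUX1 knockout cells, GFP-overexpressing cells and CUX1-overexpressing cells. CUX1 is a homeodomain transcription factor. The series asks how this factor bears on adipocyte differentiation, and the libraries allow loss of CUX1 to be compared with control and gain of CUX1 with GFP, a fluorescent protein used as the overexpression control. Total estimated counts were 31185886, 25176517 and 27981428 in the control libraries, 25153116, 25644486 and 28654800 in knockout, 18133184, 14013303 and 16166028 in GFP, and 20198626, 28289934 and 20290931 with CUX1 overexpression. The GFP libraries, although the shallowest, had counts for the most genes (18910 to 19185, against 17666 to 17869 with CUX1 overexpression, 17039 to 17714 in control and 16740 to 17294 in knockout).

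CUX1 itself (ENSG00000257923.10, chromosome 7, 101815904 to 102283958 on the plus strand of GRCh38) followed the labels in every library. It measured 137 ± 7.40 CPM in control and 46.2 ± 1.52 CPM in knockout (SD, n = 3 each), a log2 fold change of -1.57 (SE 0.06, edgeR adjusted p = 2.36e-05), so that transcripts assigned to the gene remained in the knockout libraries. With overexpression it rose from 104 ± 1.14 to 4106 ± 133 CPM (SD, n = 3 each), a log2 fold change of 5.30 (SE 0.04, edgeR adjusted p = 1.34e-11).

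**Figure D1:**
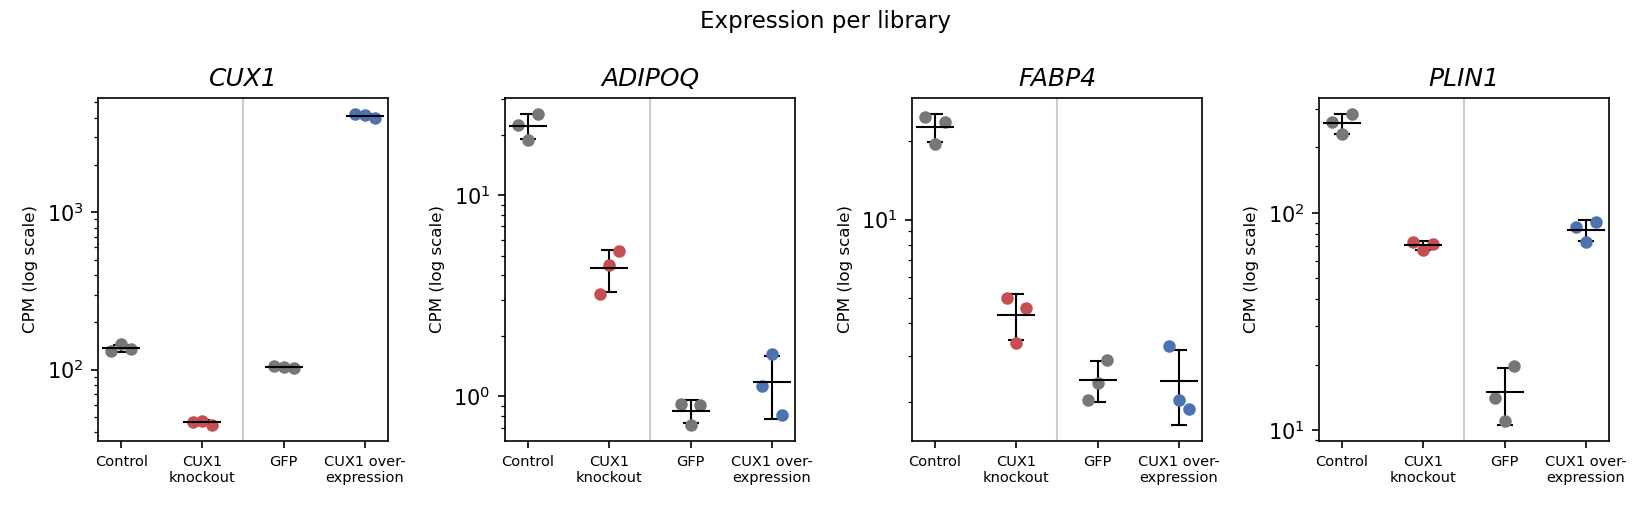
CPM (log scale) of CUX1, ADIPOQ, FABP4 and PLIN1 in each library of the 4 groups, scaled within each comparison, with points for libraries and bars for the mean and SD of 3 libraries. CUX1 averaged 137 CPM in control, 46.2 in knockout, 104 in GFP and 4106 with overexpression, and FABP4 measured 4.31 CPM in knockout and 22.7 in control but 2.43 CPM in GFP and 2.40 with CUX1 overexpression.

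Loss of CUX1 was accompanied by lower expression of genes of the mature adipocyte. FABP4, the adipocyte fatty acid binding protein, fell from 22.7 ± 2.79 to 4.31 ± 0.852 CPM (log2 fold change -2.39, SE 0.19, edgeR adjusted p = 0.000776, n = 3 per group). ADIPOQ, which encodes the adipokine adiponectin, fell from 22.2 ± 3.27 to 4.34 ± 1.03 CPM (log2 -2.35), and PLIN1, a coat protein of lipid droplets, from 258 ± 27.5 to 71.0 ± 3.27 CPM (log2 -1.86). In the list of mature adipocyte and lipid droplet genes, 12 of 28 tested members were lower, 0 were higher and 16 did not pass, with a median log2 fold change of -0.63. Adjusted over the list alone, 18 were lower and 1 was higher. The list passed camera (adjusted p = 8.42e-46) and kept its call with an estimated correlation (adjusted p = 0.0271). Other members that fell were PLIN4 (log2 -1.38), the glycerol phosphate dehydrogenase GPD1 (-1.69), FABP5 (-1.82), the triglyceride lipase PNPLA2 (-0.78), GPAM (-0.68) and CIDEC (-0.31). G0S2 (-0.52), TUSC5 and PCK1 (1.54 to 0.314 CPM) also fell. The calls of GPAM, CIDEC, G0S2, TUSC5 and PCK1 were lost without at least 1 library, in 1, 4, 5, 1 and 6 of the 6 omissions.

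Of 15 tested de novo lipogenesis genes, which serve fatty acid synthesis and desaturation, 5 were lower and 0 higher (8 lower adjusted over the list alone), among them the desaturases SCD (log2 -1.05, SE 0.14) and FADS1 (-1.0, SE 0.09), the elongase ELOVL5 (-0.48), ACACB (-0.71) and ACLY (-0.28), the last 2 losing their calls in 3 and 6 of the 6 omissions of a library. camera called the list lower (adjusted p = 3.87e-11), but not with an estimated correlation (adjusted p = 0.161). The adipogenic transcription factor list was also called lower by camera (adjusted p = 1.57e-05, or adjusted p = 0.0547 with an estimated correlation), with a median of -0.22 over 22 genes. Only KLF15 of that list passed the test for single genes (-0.33, adjusted p = 0.0309, lost in 5 of the 6 omissions), and 8 members were lower and 1 higher adjusted over the list alone. CEBPA (-0.35, adjusted p = 0.0543) and PPARG (-0.28, adjusted p = 0.149), the factors that drive terminal adipogenesis, did not pass. Of 23 cholesterol biosynthesis genes 0 passed edgeR, 5 had an unadjusted p under 0.05 and DESeq2 called 1. Of 26 fatty acid oxidation and TCA cycle genes 0 passed edgeR, 4 had an unadjusted p under 0.05 and DESeq2 called 0. Adjusted over the list alone, both counts were again 0.

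Target genes of p53 formed the other list that was lower under both camera settings. Of 24 tested, 7 were lower and 0 higher (14 lower adjusted over the list alone), with a median of -0.27 (camera adjusted p = 2.98e-14, and adjusted p = 0.0271 with an estimated correlation). They were the cell cycle inhibitor CDKN1A (log2 -0.44, SE 0.05), MDM2 (-0.42), RRM2B (-0.54), FDXR (-0.50), GADD45A (-0.48), TNFRSF10B (-0.33) and ZMAT3 (-0.29). CDKN1A alone of these stayed past the threshold without each library in turn, whereas the list stayed past camera in each case. Smaller shifts were called by camera for insulin signalling (2 of 16 lower, PDE3B and GYS1), WNT targets (3 of 12 lower, DKK1, CCND1 and APCDD1), hypoxia and glycolysis (1 of 19 lower, LDHA) and CUX1 with related homeobox genes (1 of 8 lower, CUX1 itself), and for cytosolic ribosomal proteins, which were higher by a median of 0.04 (1 of 34, RPL37). These calls were lost, at adjusted p = 0.152, 0.161, 0.221, 0.0547 and 0.561 with an estimated correlation, in that order. Counts higher and lower adjusted over the list alone were 1 and 5 for insulin signalling, 0 and 3 for WNT, 0 and 4 for hypoxia, 0 and 1 for the homeobox list and 6 and 0 for ribosomal proteins. The homeobox list holds the manipulated gene and was not tested without it, so its call tells nothing beyond the manipulation. PDE3B, GYS1, CCND1, APCDD1, LDHA and RPL37 lost their calls in 5, 5, 3, 6, 5 and 4 of the 6 omissions of a library, whereas DKK1 kept its call. The insulin and WNT list calls also ended without control replicate 2, the hypoxia call without control replicate 1 or knockout replicate 2, and the ribosomal protein call without knockout replicate 1.

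Matrix genes included increases. Of 31 extracellular matrix genes, 5 were higher and 0 lower, the collagen VI chains COL6A1, COL6A2 and COL6A3 (log2 0.19, 0.23 and 0.25), THBS2 (0.33) and ELN (0.31), but the list as a whole had a median of 0.01 and was not called (camera adjusted p = 0.277). Adjusted over the list alone, 7 were higher and 4 lower. Of 18 progenitor genes, CD44 (0.25) and NT5E (0.18) were higher, whereas THY1 (-0.52) and GSN (-0.45) were lower. Of 18 TGF-beta response genes, 2 were higher, IGFBP3 (0.52) and CYR61 (0.69), and 2 were lower, among them TGFBI (-0.23). Among 17 glucocorticoid response genes, 5 were lower, including MT1X (-0.48), MT2A (-0.44) and DUSP1 (-0.36), and SGK1 was higher (0.63). None of these 3 lists was called, and adjusted over the list alone they held 5 higher and 4 lower, 2 and 3, and 3 and 6. Of the matrix, progenitor, TGF-beta and glucocorticoid genes named here, COL6A2, THY1, GSN, IGFBP3, CYR61, MT1X and MT2A kept their calls without each library in turn and the others did not. Among markers of other cell types, 1 pericyte gene (NOTCH3, -0.79) was lower and 1 Schwann cell gene (NGFR, 0.67) higher, and NGFR lost its call in all 6 omissions. In these lists 1 pericyte gene was lower, 2 Schwann cell genes were higher and 1 skeletal muscle gene was lower when adjusted over the list alone. Among 5 endothelial, 4 leukocyte, 2 mesothelial and 1 skeletal muscle gene tested, 0 passed edgeR over all genes and 0 passed DESeq2, with 1, 0, 0 and 1 at an unadjusted p under 0.05.

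Other lists moved little in knockout. Of 27 cell cycle genes, TYMS, which encodes thymidylate synthase, fell (-0.74) and the rest did not pass. Of 18 inflammatory genes complement C3 fell (-0.34), and of 8 osteogenic and chondrogenic genes MGP rose. Of 25 interferon-stimulated genes IFIT2 passed, with no counts in knockout and 3.12 ± 1.45 CPM in control. No member passed edgeR among 18 repressors of adipogenesis, 8 thermogenic, 14 contractile, 18 unfolded protein response and 13 mitochondrially encoded genes, of which 4, 2, 4, 3 and 0 had an unadjusted p under 0.05. DESeq2 called TWIST1, WNT5A and ZNF521 among the repressors, LMOD1 and MYLK among the contractile genes and 0 in the other 3 lists. Adjusted over the list alone, 2 contractile genes were higher, 2 repressors were higher and 2 lower, and counts were 0 in the other 3 lists. In the same way, counts higher and lower were 0 and 1 for cell cycle, 0 and 1 for inflammatory, 1 and 0 for osteogenic and 1 and 1 for interferon-stimulated genes. Medians and means of some uncalled lists differed in sign, with medians of -0.05 for thermogenic, 0.03 for cell cycle and -0.49 for endothelial genes and means of 0.09, -0.05 and 0.01. The interferon-stimulated list had a median of 0.01 and a mean of -0.20 that rests on the fitted fold change of IFIT2 over 0 counts, and without IFIT2 the mean was 0.18. The progenitor median was 0.10 and its mean 0.02, while camera gave the direction as lower (adjusted p = 0.999).

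The largest increases in knockout among genes eligible by level and separation were TMEM176A (log2 2.56, from 0.693 to 4.11 CPM), ZNF704 (2.14), TMEM176B (2.14), UNC13D (1.72), MGP (1.55, from 21.9 to 64.1 CPM), AADAC (1.40), DPT (1.32, from 29.1 to 72.4 CPM), JAK2 (1.13), GLDN (1.09) and CCBE1 (1.09). MGP and DPT encode matrix proteins. The largest decreases were DCAF1 (-2.79), FABP4, ADIPOQ, PLIN1, FABP5, TUSC5 (-1.77), the potassium channel KCNK3 (-1.72), GPD1, CLCA2 (-1.60) and CUX1. TMEM176A and TMEM176B are neighbouring related genes whose reads may be divided by the counting. Without individual libraries in turn, the calls of TMEM176A, MGP, DPT, FABP4, ADIPOQ, PLIN1, FABP5, GPD1, CLCA2 and CUX1 all held, whereas TUSC5 and KCNK3 lost theirs without control replicate 3, and the other 8 lost theirs in 3 to 6 of the 6 omissions. DCAF1 moved to -3.45 without knockout replicate 1.

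In total, edgeR's quasi-likelihood test called 284 of 13913 genes in knockout (2.04%), 128 higher and 156 lower, of which 11 and 25 changed at least 2-fold. Knockout and control libraries did not overlap in 20.3% of genes, where chance gives 10%. At an unadjusted p under 0.05 there were 2014 genes. Leaving out any 1 library lowered the counts, to 43 (without control replicate 1) to 82 higher and to 69 (without control replicate 3) to 111 lower, and DESeq2 called 374 higher and 400 lower. Of the 64 named genes past the threshold, 35 stayed past it without each library in turn and 29 did not.

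In cells overexpressing CUX1, compared with GFP, the lists of interferon-stimulated and of inflammatory genes were lower and the extracellular matrix list was higher, by medians of -2.65, -2.30 and 0.84. Of 14350 genes tested, 6838 (47.7%) were called, 3516 higher and 3322 lower, of which 1058 and 1222 changed at least 2-fold. Libraries of the groups did not overlap in 57.7% of genes, where chance gives 10%. The split of calls rests on the scaling: TMM factors were 1.08 to 1.09 in GFP and 0.917 to 0.922 with CUX1 overexpression, and without these factors the median of all genes shifted from -0.01 to -0.25 and 2171 genes were higher and 5376 lower. Calls were then 28.8% higher, against 51.4% with the factors, and changes are reported relative to the TMM scaling.

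Extracellular matrix genes were the list with the smallest camera p. Of 31 tested, 23 rose and 6 fell, with the same counts adjusted over the list alone and a median of 0.84 (camera adjusted p = 1.60e-33, and adjusted p = 0.0437 with an estimated correlation). Collagen I genes were prominent: COL1A1 rose from 299 to 3241 CPM (log2 3.44, SE 0.07) and COL1A2 from 1478 ± 73.5 to 6322 ± 41.5 CPM (log2 2.10, SE 0.04, edgeR adjusted p = 2.22e-09, n = 3 per group). TNC (2.77), COL5A1 (2.5), COL6A1 (1.30) and ELN (4.36) rose, while the collagenase MMP1 (-3.38), MMP3 (-0.81) and POSTN (-1.46, a call lost in 5 of the 6 omissions of a library) fell. Contractile genes rose in 11 of 13 with 0 falling (median 1.26, camera adjusted p = 3.58e-07, but adjusted p = 0.0571 with an estimated correlation), among them LMOD1 (4.39), TAGLN (2.08), ACTA2 (1.57) and MYL9 (1.26). In the osteogenic and chondrogenic list COMP (3.67), ALPL (4.16) and MSX2 (2.04) rose, SPP1 was lower (0.0358 against 2.66 CPM), and 3 of 7 did not pass (camera adjusted p = 1.44e-06, and adjusted p = 0.0437 with an estimated correlation). Progenitor genes rose in 10 and fell in 7 of 18 (camera adjusted p = 0.000214, but adjusted p = 0.0571 with an estimated correlation), with increases of THY1 (4.04), MFAP5 (2.96), GSN (1.82) and PDGFRA (1.18).

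Of 26 tested mature adipocyte genes, 11 rose, 3 fell and 12 did not pass (median 0.68, camera adjusted p = 0.00142, but adjusted p = 0.203 with an estimated correlation). CFD, the adipokine adipsin, rose from 22.9 ± 1.27 to 446 ± 21.3 CPM (log2 4.28, SE 0.07, edgeR adjusted p = 9.98e-10, n = 3 per group). PLIN1 (2.47), PLIN4 (1.37), CIDEC (1.71), DGAT2 (1.15) and ACSL1 (1.16) rose, while PLIN2 (-0.79), G0S2 (-1.21) and FABP5 (-1.06) fell. ADIPOQ (0.48, SE 0.46, adjusted p = 0.415) and FABP4 (-0.02, SE 0.36, adjusted p = 0.968) did not pass, at 1.18 and 2.40 CPM with CUX1 overexpression. Adipogenic factors rose in 14 and fell in 6 of 23 (camera adjusted p = 0.0398, but adjusted p = 0.150 with an estimated correlation), with CEBPA (1.88), SREBF1 (1.53), RXRA (1.07) and KLF9 (0.83) higher, CEBPB (-0.50) lower and PPARG at 0.47 (adjusted p = 0.0538). The adipogenic factor call ended without scaling factors (adjusted p = 0.0988).

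Cholesterol biosynthesis genes rose in 20 of 23 with 0 falling, including INSIG1 (1.52) and FDPS (0.87), with a median of 0.83 (camera adjusted p = 8.75e-07, but adjusted p = 0.0582 with an estimated correlation). De novo lipogenesis genes rose in 8 of 15 with 0 falling, including SCD (2.20), FADS2 (1.19), ELOVL5 (0.95) and ACLY (0.70), and camera called the list (adjusted p = 0.000218, but adjusted p = 0.121 with an estimated correlation). Fatty acid oxidation and TCA cycle genes rose in 17 and fell in 1 of 26, with IDH2 (2.76), HADH (1.71) and SDHA (0.84) (camera adjusted p = 0.00511, but adjusted p = 0.159 with an estimated correlation). Hypoxia and glycolysis genes rose in 12 and fell in 1 of 20, with ADM (2.37), NDRG1 (1.68), P4HA1 (1.23) and TPI1 (0.98) (camera adjusted p = 2.36e-06, and adjusted p = 0.0473 with an estimated correlation).

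Of 27 interferon-stimulated genes 22 fell, 0 rose and 5 did not pass (23 fell adjusted over the list alone), with a median of -2.65 (camera adjusted p = 5.91e-24, and adjusted p = 0.0437 with an estimated correlation). IFI6 fell from 808 ± 40.7 to 26.4 ± 0.849 CPM (log2 -4.93, SE 0.06, edgeR adjusted p = 3.92e-10, n = 3 per group), and IFI27 (-4.17), IFIT1 (-3.91) and OAS2 (-2.65) fell too. Of 23 NF-kappaB and inflammatory genes 19 fell and 1 rose, with a median of -2.30 (camera adjusted p = 6.55e-19, and adjusted p = 0.0437 with an estimated correlation). The growth factor CSF3 fell from 310 ± 6.82 to 11.9 ± 1.42 CPM (log2 -4.70), and the chemokines CXCL1 (-2.31), CXCL2 (-2.30) and CXCL3 (-3.27) fell. Of 20 unfolded protein and integrated stress response genes 11 fell and 3 rose, with a median of -0.73 (camera adjusted p = 1.18e-09, and adjusted p = 0.0473 with an estimated correlation). SLC7A11 (-4.32), ATF3 (-3.65), TRIB3 (-3.44) and ASNS (-2.13), which respond to amino acid limitation through ATF4, fell. With all 12 libraries scaled together, the interferon-stimulated list lay a median of 2.24 above control in GFP and at -0.09 with CUX1 overexpression, the inflammatory list at 3.35 and 1.84 and the stress response list at 1.23 and 0.76. Of the lists that were higher with CUX1, extracellular matrix lay at -0.84 in GFP and 0.10 with CUX1, contractile at -1.60 and -0.45, mature adipocyte at -1.81 and -1.25, cholesterol at -0.09 and 0.62 and hypoxia genes at 0.31 and 0.85. All these values also hold the difference between the experiments. The inflammatory gene that rose was complement C3 (1.43). Beside these lists, 3 of 5 tested leukocyte markers were lower with CUX1, CSF1R (-4.50, or -5.51 without CUX1 overexpression replicate 3), CD14 (-2.20) and CD68 (-0.21).

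RNA composition differed between the same groups. All 13 mitochondrially encoded mRNAs rose with CUX1 (median 0.88, camera adjusted p = 6.16e-10, but adjusted p = 0.200 with an estimated correlation), and mitochondrial genes held 1.34% to 1.54% of counts in GFP and 2.18% to 2.51% with CUX1. Cytosolic ribosomal protein genes rose in 22 and fell in 3 of 34 with a median of 0.28, which was 0.04 without scaling factors, where RPS2, RPS14, RPL27 and RPL35 turned negative (camera adjusted p = 9.31e-06, but adjusted p = 0.258 with an estimated correlation). The list of CUX1 and related homeobox genes was called through CUX1, HOXC8 (0.48) and HOXC10 (0.47), with adjusted p = 0.0571 with an estimated correlation. This list holds the manipulated gene and was not tested without it, so the call is at least partly given by the manipulation. ONECUT2 was lower (-2.34, adjusted p = 0.0474), a call that ended without GFP replicate 3 (log2 -0.63, adjusted p = 0.430) and without any of the 3 CUX1 overexpression libraries (adjusted p = 0.0929 to 0.133).

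Lists that camera did not call in this comparison still held called members in both directions, namely repressors of adipogenesis (4 higher and 7 lower of 19, with SNAI2 at 0.93 and HES1 at -1.70), insulin signalling (6 and 8 of 17, with GYS1 at 1.17 and IRS2 at -0.81), TGF-beta response (7 and 7 of 18, with LTBP2 at 1.89 and CTGF at -2.88), WNT targets (5 and 4 of 12, with APCDD1 at 4.36 and MYC at -0.79), p53 targets (9 and 9 of 24, with GDF15 at -3.24), glucocorticoid response (8 and 7 of 17, with GLUL at 2.13 and PDK4 at -2.52), cell cycle (3 and 6 of 25) and thermogenic genes (5 and 3 of 13, with ELOVL3 at 2.01 and DIO2 at -2.13). Signs differed within several of these lists. Medians for thermogenic, insulin, TGF-beta, WNT, p53 and glucocorticoid lists were -0.57, -0.01, 0.12, -0.16, 0.03 and 0.16, their means -0.04, 0.01, 0.21, 0.26, -0.14 and -0.06, and camera's directions up, down, down, up, down and up, none of them past its threshold. Among other cell markers, endothelial genes were lower in 2 of 7, pericyte genes higher in 2 of 6 and Schwann cell genes higher in 1 of 4 (NGFR, 2.83), with 0 of 2 mesothelial and 0 of 1 skeletal muscle genes called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05. DIO2 and VWF lost their calls in 2 and 4 of the 6 omissions of a library and moved to -2.81 and -3.58 without CUX1 overexpression replicates 1 and 2. Endothelial EGFL7 (-0.97) and VWF (-2.36) fell, and pericyte NOTCH3 (0.88) and ABCC9 (0.91) rose. Adjusted over the list alone, counts higher and lower were 16 and 7 for adipogenic factors, 9 and 0 for lipogenesis, 22 and 0 for cholesterol synthesis, 17 and 2 for oxidation and TCA cycle, 12 and 2 for hypoxia, 3 and 13 for the stress response, and 4 and 1 for both the osteogenic and the homeobox list. They were 8 and 7 for TGF-beta, 3 and 4 for cell cycle, 9 and 10 for p53 and 9 and 7 for glucocorticoid genes. Counts were 0 and 23 for interferon-stimulated, 0 and 1 for endothelial and 2 and 2 for pericyte genes, and as over all genes tested in the other lists.

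The largest increases included genes near or below detection in GFP. FMO1 and BPIFB4 had 0 counts in all GFP libraries and were at least 103-fold and 64.2-fold higher with CUX1. PLA2G2A (log2 7.03), KCND3 (5.34), CUX1, MXRA5 (5.12), HPR (0.148 CPM in GFP, under the floor of 3 counts, and 5.16 with CUX1), FMO2 (5.0), BPIFB1 (5.0) and IGF1 (4.83) followed. IGF1, insulin-like growth factor 1, rose from 47.9 ± 3.73 to 1366 ± 81.2 CPM. Among the largest decreases, SHTN1 had 1 count with CUX1 and 271 with GFP, a ratio of 326 (exact Poisson 95% interval 58.1 to 12935), and NPM1P40 had 2 and 281, a ratio of 169 (46.4 to 1404). CCDC150P1 (8.20 CPM in GFP and 0.0717 with CUX1, under the floor), FCGR1B (-6.08), DCLK2 (-5.74), FGF22 (-5.54), LILRB3 (-5.43), MAP2 (-5.20), RSAD2 (-5.00) and IFI6 completed the list. Leaving out 1 library moved PLA2G2A to 7.98 (without GFP replicate 3) and MAP2 to -6.53 (without CUX1 overexpression replicate 1). HPR, FCGR1B, LILRB3 and the pseudogenes NPM1P40 and CCDC150P1 have close paralogs or parent genes, and their values are uncertain.

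**Figure D2:**
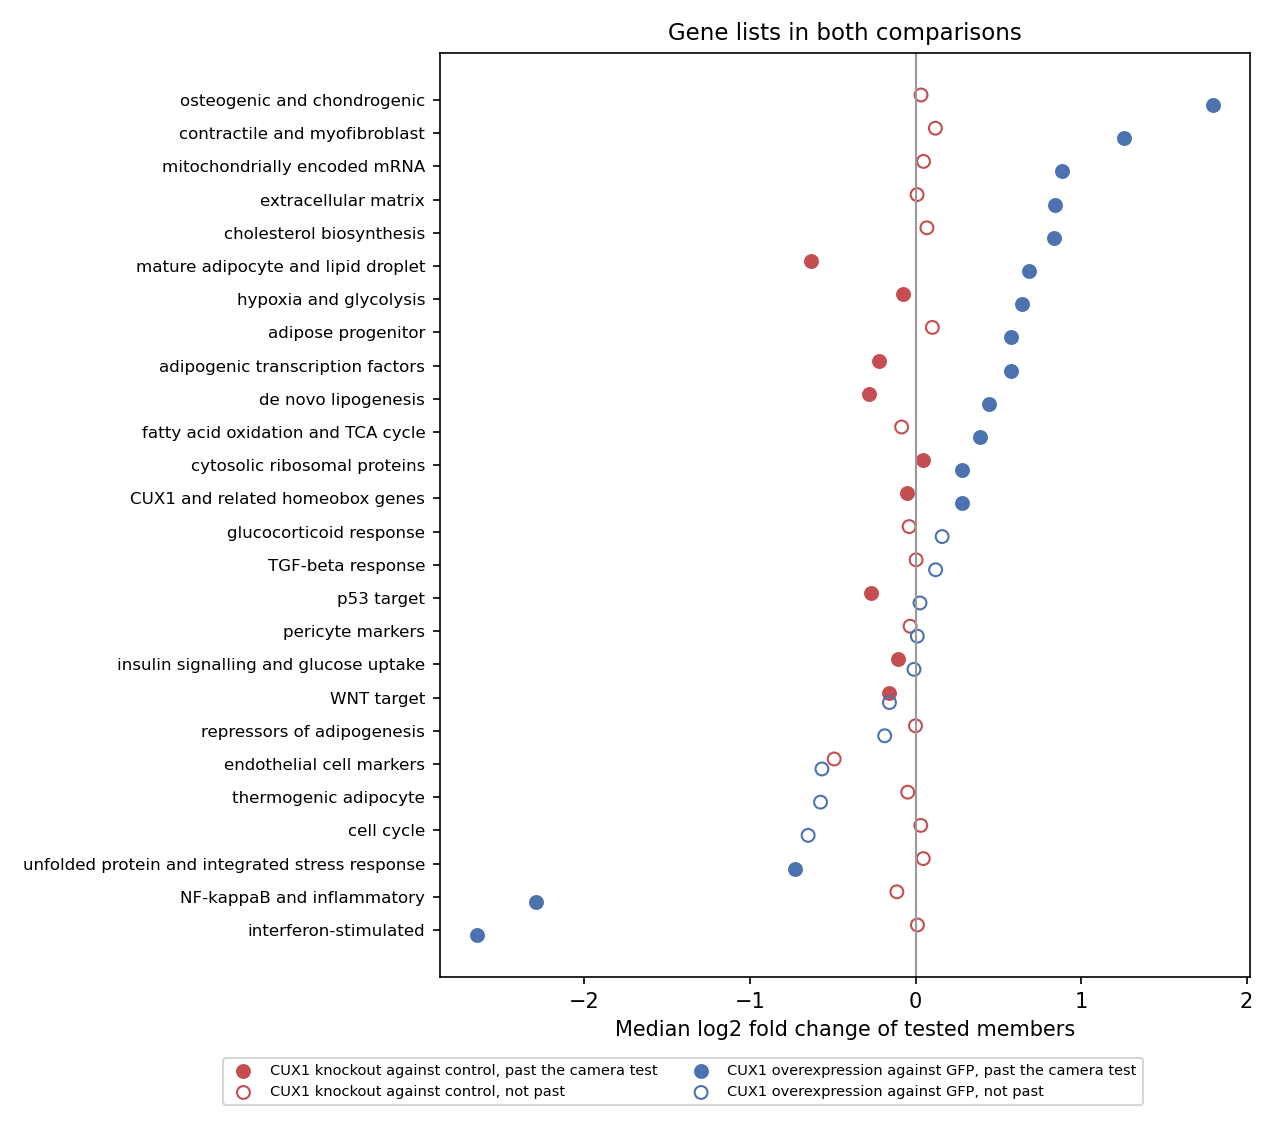
Median log2 fold change over the tested members of each gene list that camera tested in both comparisons, for the knockout comparison (red) and the overexpression comparison (blue), with filled points for lists past camera at an adjusted p under 0.05 and open points for the others. The mature adipocyte list lies at -0.63 in knockout and 0.68 with overexpression, and the interferon-stimulated list at -2.65 with overexpression.

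Whether the effects of loss and gain of CUX1 differed was tested directly. The difference of the log2 fold changes, knockout minus overexpression, passed for 4945 of 15264 genes, with the knockout effect above in 2125 and below in 2820. For PLIN1 the difference was -4.34 (SE 0.21), for SCD -3.25 (SE 0.18), for FABP4 -2.37 (SE 0.34) and for ADIPOQ -2.85 (SE 0.39). For CDKN1A it was -0.48 (SE 0.06). All 107 genes called in both with opposite direction, and 65 of the 112 called with the same direction, were among the 4945.

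Genes called in both comparisons were counted to ask whether loss and gain of CUX1 moved the same genes, and in which directions. Of 13498 genes tested in both, 219 were called in both, 107 in opposite directions and 112 in the same direction. Genes lower in knockout and higher with overexpression numbered 88, where independent lists give 40.0 (Fisher's exact test, two-sided, p = 4.26e-16) and draws matched on expression level a median of 66, with 78 as the upper end of their central 95%. They included the amine oxidase AOC3 (log2 -1.54 and 1.39), PLIN1 (-1.86 and 2.47), PLIN4 (-1.38 and 1.37), the lipid transport protein APOE (-0.71 and 4.24) and CUX1. Genes higher in knockout and lower with overexpression numbered 19, where independent lists give 28.3 (Fisher's exact test, two-sided, p = 0.0533), with CHI3L1 (0.57 and -1.10), TM4SF1 (0.99 and -2.31), COLEC12 (0.57 and -0.71), CYR61 (0.69 and -1.18) and SGK1 (0.63 and -1.53).

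Genes higher under both loss and gain of CUX1 numbered 80, where independent lists give 32.9 (Fisher's exact test, two-sided, p = 1.31e-18) and draws matched on expression level a median of 52, with 63 as the upper end of their central 95%. They included the secreted or matrix proteins DPT (1.32 and 1.92), CTHRC1 (0.74 and 1.55), AEBP1 (0.36 and 1.02), CCDC80 (0.41 and 1.19) and IGFBP3 (0.52 and 2.56). Genes lower in both numbered 32, where independent lists give 34.5 (Fisher's exact test, two-sided, p = 0.698), with ZBED3 (-0.85 and -1.09), TFRC (-0.79 and -0.33), FABP5 (-1.82 and -1.06), NAMPT (-0.56 and -0.96) and MT2A (-0.44 and -1.20). These Fisher tests treat genes as independent, which they are not. Without control replicate 1, 52 genes were called with opposite and 37 with the same direction. Among genes called in both, the test for an association of the directions in the comparisons did not pass (Fisher's exact test, two-sided, p = 0.203). Across all 13498 genes, Pearson's correlation of the log2 fold changes was -0.019 and Spearman's -0.00215.

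**Figure D3:**
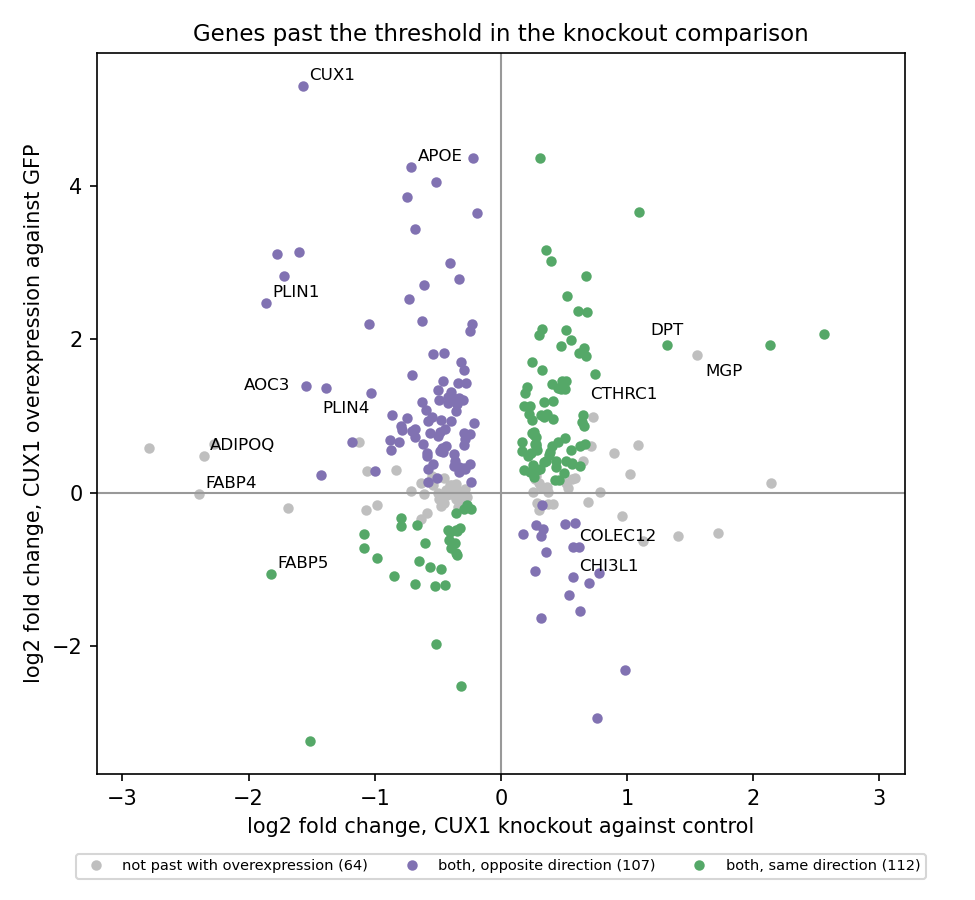
Log2 fold change in knockout (x) against log2 fold change with overexpression (y) for the genes called in knockout, in purple for the 107 called in both comparisons with opposite direction, green for the 112 with the same direction and grey for those not called with overexpression, without IFIT2, which had no counts in knockout. PLIN1 and AOC3 lie left of and above the origin, whereas FABP4 and ADIPOQ lie near 0 on the y axis.

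**Figure D4:**
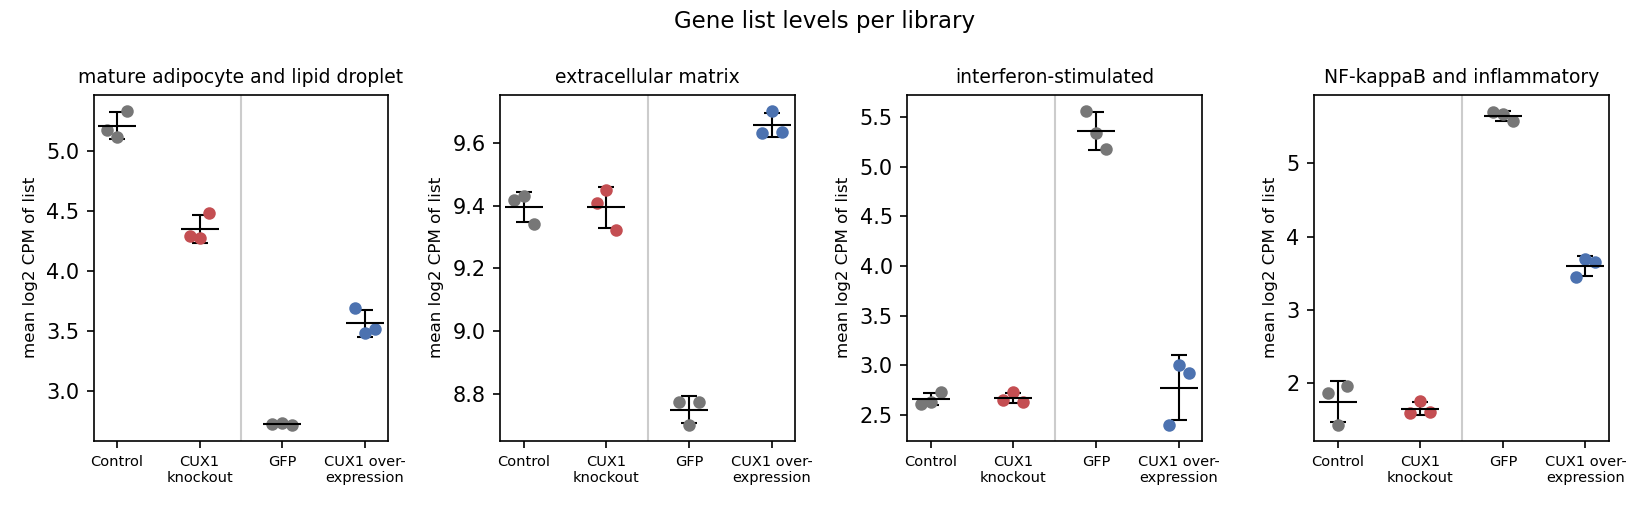
Mean log2 CPM over the genes of 4 lists in each library, scaled over all 12 libraries, with points for libraries and bars for the mean and SD of 3. The grey line parts the experiments, which also differ in how the cells were handled, so that levels on either side of it are not tested against each other.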

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

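The relabelling of libraries, the gene length test of adipocyte genes and the matched draws for genes higher in both comparisons were set out before their results were seen, whereas the tests of GFP levels, depth and leukocytes, of single libraries and of the share of adipocytes were chosen afterwards.

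The effects of loss and gain of CUX1 differed in 4945 genes by the test of the difference itself. Among 100 splits of the libraries, the real one included, 2 gave as many genes and the highest other gave 4950. The split with 4950 genes exchanged the control and knockout labels and kept those of overexpression. The 14 other splits that kept the overexpression labels gave 4354 to 4950 genes and all others drawn at most 2, so the share of splits reflects how often the overexpression labels were kept. Splits that kept these labels also kept the real overexpression effect, so they do not show what equal effects would give. The splits therefore cannot exclude chance for a difference between the effects of knockout and overexpression. Nor is the count a measure of what the knockout adds.

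Within each comparison the 6 libraries allow 10 splits, which are too few for a share under 0.05. edgeR called 284 genes in knockout and 6838 with overexpression, and the highest of the other splits gave 0 in each comparison. At an unadjusted p under 0.05 the other splits gave 483 to 652 genes against 2014 in knockout and 153 to 205 against 7866 with overexpression. camera with the preset correlation called 9 lists in knockout and 16 with overexpression, each count including the homeobox list that holds CUX1. The highest of the other splits gave 5 and 11. Lists were thus called under exchanged labels too, at a median of 2 and 9 lists per split. Each other split joins 2 libraries of a group with a library of the other group. It therefore keeps part of the real difference and widens the spread within its groups, so these gene and list counts do not measure false calls. camera with an estimated correlation was not run on the splits. It was the stricter test and kept 2 of the 9 and 6 of the 16 list calls, whereas fry kept 8 and 16.

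Interferon-stimulated genes were lower with CUX1 than with GFP (median -2.65), and after thinning to equal depth the median was -2.70 with 23 of 26 genes lower. Levels were already scaled to the library totals, so thinning could hardly have moved this median and decides little about sequencing depth. With all 12 libraries scaled together, the list lay 2.24 above control in GFP and at -0.0884 with CUX1, as raised levels in the GFP libraries would give, but the experiments differ in handling, and a rise in both arms that CUX1 lowered would give the same. For inflammatory genes these values were 3.35 and 1.84. Every list called higher with CUX1 except hypoxia and glycolysis (0.31) lay below control in GFP. Medians were -1.81 for mature adipocyte, -1.60 for contractile, -1.47 for mitochondrially encoded and -1.12 for osteogenic genes. Adipogenic factors lay at -0.89, extracellular matrix at -0.84, ribosomal proteins at -0.78 and progenitor genes at -0.54. Lipogenesis lay at -0.39, the homeobox list at -0.36, oxidation and TCA cycle at -0.32 and cholesterol at -0.09. For none of the lists in this paragraph can GFP levels off control and an effect of CUX1 be told apart without untreated cells of the same experiment. Leukocytes in the GFP libraries may add to the pattern and stay open: CD68 (181 CPM), CSF1R (7.49) and CD14 (6.54) exceeded 0.1 of the median interferon excess of 26.8 CPM and were lower with CUX1. FCGR1B (14.2 CPM in GFP) and LILRB3 (15.8) were lower too. They were taken from the largest decreases and not from the leukocyte list, and their values are uncertain, so they add no support. Against leukocytes, the median over the 12 leukocyte markers was 0.336 CPM in GFP, PTPRC was at 0.426 CPM, LYZ at 0.148, and TYROBP, CD3E and MS4A1 had 0 counts, while 4 of the 12 also passed the low-count filter in control and knockout cells.

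Mature adipocyte genes were lower in knockout (median -0.63), and without each library in turn the median stayed between -0.76 and -0.60, which argues against a single library as the cause. Of the 28 members 27 had a length, with a median of -0.58, outside the range of -0.09 to 0.10 that holds the central 95% of 10000 random lists matched on gene length. A lower share of adipocytes would raise the markers of the other cells, by an amount that depends on that share, which was not measured. Of 18 progenitor markers THY1 (-0.52, and -0.46 at the nearest to 0 without a library) and GSN (-0.45) were lower. CD44 (0.25) and NT5E (0.18) were higher, these 2 losing their calls in 5 and 6 omissions. Because the rise could be too small to see, these few markers cannot decide the question. A lower share of adipocytes stays open, with or without a change within the progenitor cells that hides it. Differences in how the knockout and control cells were derived also stay open and were not tested. That loss of CUX1 lowered adipocyte gene expression in these cultures may therefore be put forward only as a hypothesis.

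Genes higher under both loss and gain of CUX1 numbered 80, above the 32.9 of independent lists. Draws matched on expression level gave a median of 52, with 63 as the upper end of their central 95%, so expression level could account for part of the excess. The 80 genes lay above these draws. The draws matched the mean level only in bins, so a larger part for expression level is not excluded. Draws matched on gene length gave a median of 33 and an upper end of 43, against 79 observed among genes with a length. For the 88 genes lower in knockout and higher with overexpression, draws matched on expression level gave a median of 66 and an upper end of 78. A response to handling common to both treated groups was not tested, and genes that move together widen chance beyond these draws.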

How the results depend on the processing

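The fits to unrounded counts, without scaling factors and at equal depth were chosen after the data were seen, and all other alternatives were fixed before. CUX1 kept its direction and its call under every alternative, from -1.60 to -1.53 in knockout and 5.29 to 5.33 with overexpression without each library in turn, and at 5.06 with overexpression without scaling factors. Without the low-count filter 205 genes and 2 lists were higher in knockout, and 167 genes were called in both comparisons in opposite directions. DESeq2 called 374 genes higher and 400 lower in knockout, and 294 in opposite and 266 in the same direction in both. In 1 fit over 12 libraries 284 genes were lower in knockout. The cause of these changes was not tested. A limit of at least 2-fold, which removes smaller changes by construction, left 11 higher and 25 lower in knockout, 1058 and 1222 with overexpression, and 9 opposite and 6 same in both.

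Without each library in turn, which leaves fewer samples, knockout gave 43 to 82 genes higher and 69 to 111 lower, with 1 to 2 lists higher and 6 to 9 lower. Overexpression gave 3108 to 3209 genes higher and 2886 to 3035 lower, with 13 to 14 lists higher and 3 lower. Both comparisons shared 52 to 105 genes in opposite and 37 to 105 in the same direction, and the difference of effects passed in 4458 to 4665. The correlation of fold changes ranged from -0.037 to 0.011 (jackknife SE 0.0498). Of named genes past the threshold, 35 of 64 in knockout and 132 of 133 with overexpression kept their calls. Among named genes in knockout, 15 lost their calls under the replicate block, 5 lost their calls in 1 fit over 12 libraries, 2 with limma-voom and 1 without scaling factors, while 11 gained one with DESeq2, 7 in 1 fit over 12 libraries, 5 without the filter, 2 without scaling factors and 1 at equal depth. With overexpression 2 lost theirs without scaling factors and 1 each with limma-voom and the block. Of other list members, the block ended 11 of 17 calls in knockout and 9 of 248 with overexpression, and leaving out scaling factors ended 40 with overexpression beside the 8 that changed sign. With an estimated correlation 0 lists were higher and 2 lower in knockout, and 3 were higher with overexpression; fry called 7 lists lower with overexpression. The replicate number as a block gave 66 genes higher and 101 lower in knockout, and 55 in the same direction in both. No effect shared by libraries of the same number was seen: their deviations correlated at -0.0263 to 0.0238 in knockout and -0.0300 to -0.00352 with overexpression. The labels do not say whether a number marks a shared culture or day, so pairing is not excluded.

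Without scaling factors 2171 genes were higher and 5376 lower with overexpression, since the median of all genes fell to -0.25. NFIB (-0.0493), TECR (-0.0149), CD55 (-0.04), FN1 (-0.12), RPS2 (-0.0683), RPS14 (-0.0114), RPL27 (-0.11) and RPL35 (-0.13) then turned negative by that construction. Without the filter the median was -0.13. RLE factors, limma-voom, unrounded counts and equal depth left all gene and list counts within 1.5 times where they were computed. Floors of 0.0962 to 0.214 CPM for 3 counts limit what could be seen of rare transcripts.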

Other observations

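All 7 gene families and both tests of shared list members in this part were chosen after the data were seen, and camera was adjusted over the 7 families of a comparison. With overexpression, complement genes rose in 12 and fell in 2 of 16, with a median log2 fold change of 1.33. CFD and C3 had been seen to rise before the family was chosen, and without them and CD55, which the lists or named genes also hold, 9 of 13 rose and 2 fell (median 1.24, camera adjusted p = 0.0382 with an estimated correlation). The classical pathway proteases C1R (1.77) and C1S (1.24), their inhibitor SERPING1 (1.53) and the terminal component C7 (3.16) rose, and CFB, of the alternative pathway, fell (-0.74). C6 also passed, at 0.0699 CPM in GFP, which lies under the floor of 3 counts, and 1.48 CPM with CUX1. C4A and C4B are near-identical copies, and their values are uncertain. Genes of the insulin-like growth factor axis rose in 7 and fell in 2 of 10 (median 1.32), the ligands IGF1 (4.83) and IGF2 (3.54) among the former. Of the binding proteins, IGFBP2 (1.74), IGFBP3 (2.56), IGFBP4 (1.35), IGFBP5 (0.79) and IGFBP7 (1.30) rose and IGFBP6 (-1.45) fell. IGF1 and IGFBP3 had likewise been seen, and without them 5 of 8 rose and 2 fell (median 1.05, adjusted p = 0.0382 with an estimated correlation). Heat shock chaperones, among them the mitochondrial HSPD1 and HSPE1, fell in 12 of 13 with 0 rising (median -0.69, adjusted p = 0.0382 with an estimated correlation), including HSPA8 (-0.73), DNAJB1 (-1.29) and HSPH1 (-1.35), while HSPA1A and HSPA1B share reads and are uncertain.

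Antigen processing genes fell in 7 and rose in 1 of 12 with overexpression, with TAP1 (-1.22) and PSMB8 (-0.72) lower and PSMB10 (0.38) higher, but the list was not called (camera adjusted p = 0.0651). Aminoacyl-tRNA synthetases fell in 8 and rose in 2 of 12 (camera adjusted p = 0.00426, but adjusted p = 0.117 with an estimated correlation), with GARS (-0.96) and YARS (-0.95) lower and LARS (0.64) and IARS (0.31) higher. Lysosomal enzymes rose in 9 and fell in 8 of 19 (median 0.04, or -0.20 without scaling factors, camera adjusted p = 0.473), and proteasome core genes rose in 1 and fell in 5 of 14 (camera adjusted p = 0.263). In knockout few members passed, namely C3 among 17 complement genes, IGFBP3 (0.52) and IGFBP5 (-0.48) among 9 growth factor axis genes, HSPB1 (0.26) among 13 chaperones, IARS (-0.28) among 12 synthetases and CTSK (0.52) among 19 lysosomal enzymes. Antigen processing and proteasome core genes had 0 called by edgeR of 12 and 14 tested in knockout, with 3 and 0 at an unadjusted p under 0.05 and 0 and 0 called by DESeq2. camera did not call the 9 growth factor axis genes in knockout (adjusted p = 0.0621, or adjusted p = 0.286 with an estimated correlation). Without IGF1 and IGFBP3, the latter being the member called higher, it called the 7 remaining genes lower (adjusted p = 6.26e-05). That call was lost with an estimated correlation (adjusted p = 0.0625). camera called the lysosomal list higher in knockout (adjusted p = 0.000125), but not with an estimated correlation (adjusted p = 0.125).

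Whether the extracellular matrix and mature adipocyte lists shared more called members than the calls in each comparison give was tested within the lists. camera had not called the matrix list in knockout. Of 31 extracellular matrix genes tested in both comparisons, 5 were higher in knockout and 23 with overexpression, which gives 3.71 shared members, and 4 were higher in both (COL6A1, COL6A2, COL6A3 and ELN; Fisher's exact test within the list, two-sided, p = 1). Of 25 mature adipocyte genes, 12 were lower in knockout and 11 higher with overexpression, which gives 5.28, and 6 were both (CIDEC, GPAM, PLIN1, PLIN4, PNPLA2 and TUSC5; Fisher's exact test within the list, two-sided, p = 0.695). The matrix test could not have passed even with all 5 knockout genes shared, because 23 of the 31 genes were higher with overexpression, so it decides nothing. The adipocyte test did not detect an excess of shared members over what the calls in each comparison give. With so few genes an excess is not excluded in either list.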
